A study of Mus musculus with 8 samples.

How the data were processed

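Total RNA from AV cushions and ventricles of C57BL/6 mouse embryos at E12.5 was extracted with a Qiagen micro column kit, per the labels' protocols, and libraries were made with a stranded total RNA kit after removal of ribosomal RNA. The submitters' processing notes name Bowtie 0.12.7, a read aligner, and the mouse genome build mm9. The program that counted reads, the annotation and the strand setting are not given in the sources used here. The deposited values are raw counts per row for all 8 samples, whole numbers that sum to between 26562828 and 37694738 per library over all rows, and were taken as counts without change. The 8 deposited tables have the same content, so 1 was read, and each column was assigned to the sample of the same title. The table has 28644 rows and 22869 distinct symbols, with no row lacking a name. 3705 symbols occur on more than 1 row, and in 74.8% of the 2674 such symbols with over 500 reads the lowest row holds at least 90% of the counts of the highest row, so that the rows appear to count the same reads for several transcripts. The row with the largest total was kept for each symbol. The library totals were then between 18955733 and 26579215 counts. Because the strand setting is unknown, genes that overlap on opposite strands, such as Tsix and its partner, are uncertain, and so are genes with near-identical copies such as the globin and histone genes. No coordinates are given, because the genome build of the counts was not used here.

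Samples were grouped by tissue and genotype from their titles, with 2 libraries in each of 4 groups. Nothing in the labels says that the 2 libraries of a group come from separate embryos or litters, so p-values measure the spread between these samples, which may be technical. The 2 libraries of each group differed by far more than sampling noise, with a chi-square per degree of freedom between 45.5 and 118.3, so all 8 were used. Counts were tested with edgeR 4.0.16 in R 4.3.3: normalization by trimmed mean of M-values (TMM), filtering by expression within groups, a quasi-likelihood fit with robust empirical Bayes over all 8 libraries in 4 groups, two-sided tests and Benjamini-Hochberg adjustment, with a threshold of 0.05. The filter kept 14940 symbols, which hold 99.97% of the counts. The contrasts were mutant against wild type in cushion, the same in ventricle, their difference (the interaction), and cushion against ventricle in wild type. Standard errors are the log2 fold change divided by the root of the F statistic. Levels in CPM are counts divided by the library total after TMM scaling.

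Samples of all groups carry replicate numbers 1 and 2, and the labels do not say what a number marks. The deviations of replicate 1 from its group mean correlated between groups in all 6 pairs of groups, with Pearson r across genes from 0.341 to 0.522, and the second principal component, with 14.1% of the variance, separated replicates 1 from replicates 2. The numbers were therefore treated as a pairing seen in the data and not as one stated by the design. With 4 groups of 2 there are 8 ways to line up the numbers, so 1 of the 8 would do so by chance if the deviations follow a shared axis. Ttn took a larger share of counts in replicate 1 than in replicate 2 of every group, from 1.09% to 6.48% of counts over the libraries. Values from a fit with the replicate number as an additive term are given beside the main ones where they change a call or move a count of calls given in the text by over 1.5 times.

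29 gene lists on pathways, cell types and sample quality were fixed before the data were examined, and 28 had at least 3 measured members. 488 of the 499 listed entries were found in the table. The list of mitochondrially encoded genes had 0 measured members. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. The genes named by rule, also fixed beforehand, are Klf2, Nfatc1 and Wnt9b, the 10 largest changes in each direction that passed with separated libraries and a mean of at least 1 CPM, or where none passed the 5 smallest p-values in each direction, and up to 4 members of each list with the smallest p, leaving out from the ranked genes predicted genes and small RNAs. Transcript length and GC content came from the longest transcript per symbol in GENCODE vM21, to which 98.2% of symbols in the table were matched, through current or older names, and were used for no coordinate. The correction for GC content and length subtracts a spline fitted in each library to the deviation of log2 CPM from the gene mean, as an offset in the model. It was chosen after the data were seen.

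The tests were run on simulated counts with the real library sizes and the dispersions from the fit over all 4 groups. Each gene had the same mean in every group, taken over all 8 libraries of both tissues. In mutant cushions 50 genes were changed at each of 4 fold sizes. The shares recovered may therefore not hold for the real cushion comparison. Over 14752 genes without a block, edgeR recovered 8% of genes changed 1.5-fold, 52% at 2-fold, 92% at 4-fold and 98% at 8-fold, with 11 false calls among 136. DESeq2, over 14180 genes, gave 40 false calls among 177. With the block, over 14770 genes, edgeR recovered 52%, 92%, 100% and 100%, with 20 false calls among 192. Each fit was tested on its own simulated set, so these shares do not compare the fits. With a simulated GC trend in mutant cushions, over 14751 genes, the block fit made 315 false calls among 488 before the correction and 12 among 179 after it. Alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2 or upper-quartile scaling in edgeR, no filter or a filter at 5 CPM in 2 libraries, a fit on the compared groups alone, the replicate block over all libraries or by tissue, no robust fit, leaving out each library, and for the lists a prior count of 0.5. Added after the data were seen were sums of the rows of a symbol, all rows on their own, the GC and length correction, and the block with these, with DESeq2 and with each library left out.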

Results

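RNA was measured by total RNA sequencing in atrioventricular (AV) cushions and ventricles of mouse hearts at E12.5, a stage of embryonic development at which cushions are being remodelled. AV cushions are the swellings of the AV canal from which heart valves and septa form. Klf2 encodes a transcription factor that responds to blood flow in endothelial cells, and Nfatc1 encodes a transcription factor of the endocardium, the inner cell layer of the heart. The 8 libraries formed 4 groups of 2: wild type cushion, mutant cushion, wild type ventricle and mutant ventricle. The genotype label of the mutant samples is NfatC1+/- with Klf2 floxed on both alleles. The labels do not say whether +/- stands for the loss of 1 Nfatc1 copy or for an allele that carries a recombinase, so the mutants may differ from wild type in Nfatc1 as well as in Klf2. The control samples are labelled wild type, while the design text names mice with floxed Klf2 beside the mutants, and the series is described as a study of how Klf2 acts in cushion endocardial cells. With 1 row kept per gene symbol, library totals lay between 18955733 and 26579215 counts. 14940 symbols were tested. Levels are given as CPM, counts scaled to a common library size, and 1 CPM corresponded to at least 18.7 reads. The labels do not say whether the 2 libraries of a group came from separate embryos or litters.

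Klf2 RNA was low in every mutant library. In cushions its level was 15.1 ± 3.12 CPM (SD, n = 2) in wild type and 1.31 ± 0.927 CPM (SD, n = 2) in mutants. In ventricles it was 10.45 ± 1.78 CPM (SD, n = 2) in wild type and 0.680 ± 0.0781 CPM (SD, n = 2) in mutants. The log2 fold change was -3.54 ± 0.42 (SE) in cushions and -3.93 ± 0.45 (SE) in ventricles. Neither passed with edgeR over all genes, with adjusted p = 0.145 and 0.269, while both fell with the replicate number as a block, with adjusted p = 2.86e-05 and 4.56e-05. Wnt9b, which encodes a WNT ligand, was at 34.7 ± 0.385 CPM (SD, n = 2) in wild type cushions and 6.93 ± 0.0432 CPM (SD, n = 2) in mutant cushions. Its cushion log2 fold change of -2.32 ± 0.32 (SE) had an adjusted p of 0.145, and of 4.99e-04 with the block. Nfatc1 was at 29.0 ± 9.78 CPM (SD, n = 2) in wild type and 20.03 ± 6.90 CPM (SD, n = 2) in mutant cushions, a log2 fold change of -0.53 that did not pass (adjusted p = 0.718, and 0.0994 with the block). As the mutants carry the label NfatC1+/-, this value cannot be assigned to the loss of Klf2 alone.

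**Figure D1:**
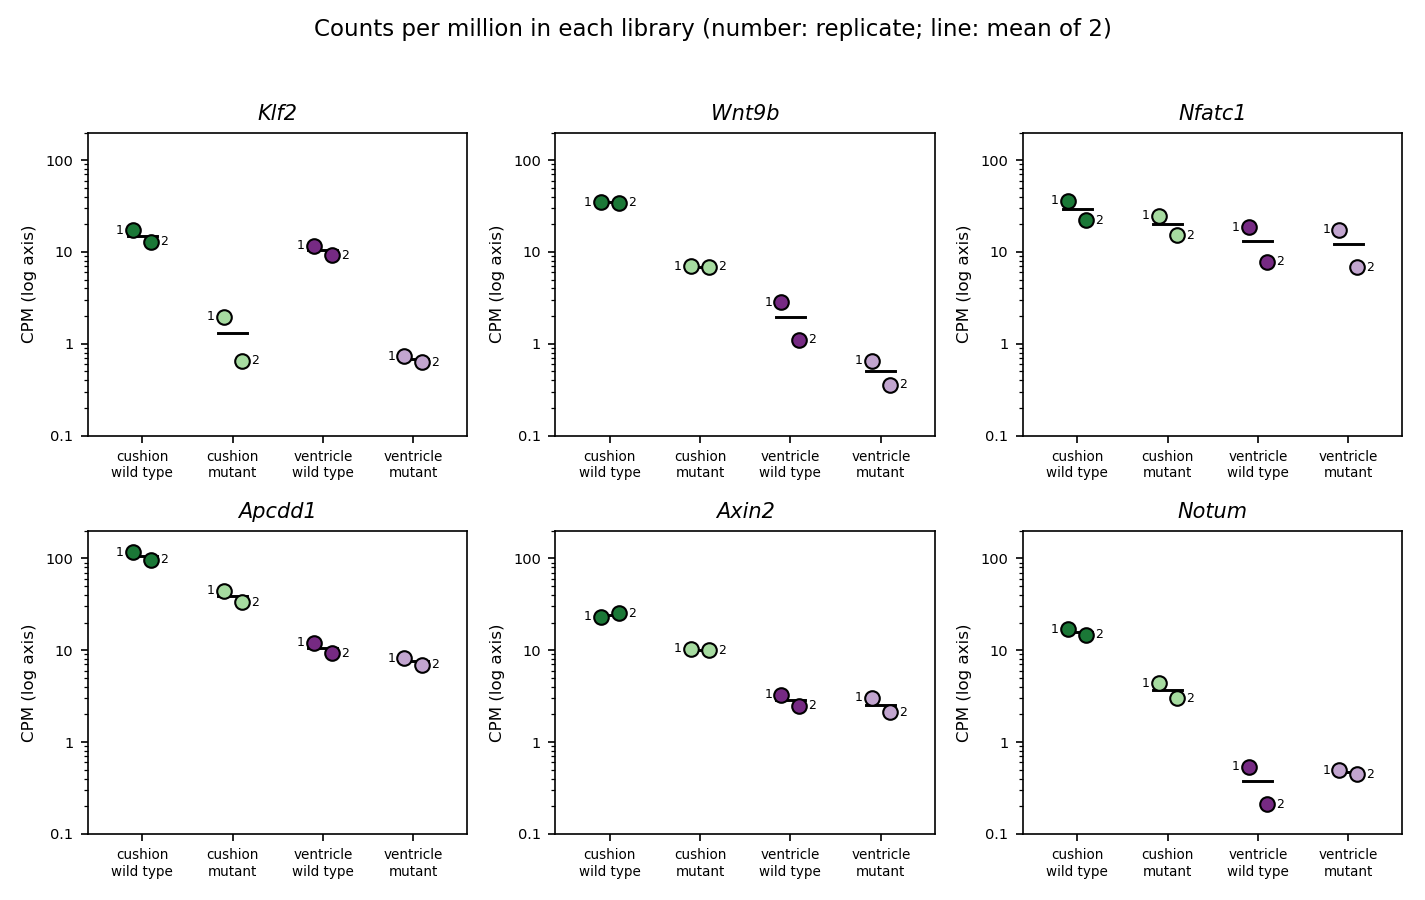
CPM (counts scaled to library size, log axis) of Klf2, Wnt9b, Nfatc1 and the WNT target genes Apcdd1, Axin2 and Notum in each of the 8 libraries, with the replicate number beside each point and a line at the mean of the 2 libraries of a group. Klf2 lies between 12.9 and 17.3 CPM in the wild type cushions and between 0.651 and 1.96 CPM in the mutant cushions.

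The comparison of mutant with wild type cushions asks how cushion RNA differs between the genotypes, which differ in Klf2 and may differ in Nfatc1. The lowest p-values among the genes lower in mutant cushions belonged to Dpt, which encodes dermatopontin, a matrix protein, and to Klf2, Apcdd1, Anxa8 and Tmem132c. Dpt was at 48.5 ± 9.28 CPM (SD, n = 2) in wild type and 15.3 ± 0.379 CPM (SD, n = 2) in mutants, and Apcdd1, a WNT inhibitor gene that WNT signalling itself induces, at 107.1 ± 14.4 CPM (SD, n = 2) and 38.9 ± 7.94 CPM (SD, n = 2). Genes of WNT feedback were lower as a group, and epicardial, leukocyte and interferon genes were higher as groups, in camera with a preset correlation. These calls were lost with an estimated correlation, with adjusted p = 0.581, 0.678, 0.768 and 0.768, and the leukocyte and interferon calls also ended without mutant cushion replicate 2 (0.311 and 0.874). The epicardial and leukocyte calls ended without wild type cushion replicate 1 (0.185 and 0.61). Among single genes higher in mutants, Plek was at 31.6 ± 5.91 CPM (SD, n = 2) in wild type and 76.4 ± 10.4 CPM (SD, n = 2) in mutants.

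No gene passed an adjusted p of 0.05 in edgeR. The smallest adjusted p was 0.0903, for Dpt, and 1699 genes had an unadjusted p under 0.05, 918 higher and 781 lower, or 3557 with the replicate number as a block, 1780 higher and 1777 lower. These were 11.4% and 23.8% of the genes tested, where no difference would give a share of about 0.05. DESeq2 called 25 genes and limma-voom 2. With the replicate number as a block, 129 genes passed, of which 44 rose and 85 fell. The block calls included Dpt with a log2 fold change of -1.66, Apcdd1 with -1.47, Anxa8 with -2.19 and Tmem132c with -1.41. Among the genes higher in mutant cushions, the block calls included Prps2 with 0.72, Ddx3y with 0.62, Plek with 1.25, Rab27b with 1.09 and Apold1 with 0.94. Of these 5, Prps2 and Apold1 passed after the GC and length correction described next, with adjusted p = 0.0232 and 0.0299, and Ddx3y, Plek and Rab27b did not. The fold change ran with transcript GC content across genes, which are not independent replicates, with a Spearman rho of -0.607. Genes that fell with the block had a median GC content of 54.6% and those that rose 43.3%, against 49.6% over all genes tested. After a correction for GC content and length, the block fit called 71 genes, of which 26 rose and 45 fell, and 45 of the 71 were among the 129. Leaving out 1 library moved the block count in every case. It was 30 or 25 without wild type cushion replicate 1 or 2, 891 or 243 without mutant cushion replicate 1 or 2, 65 or 40 without wild type ventricle replicate 1 or 2, and 640 or 543 without mutant ventricle replicate 1 or 2.

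**Figure D2:**
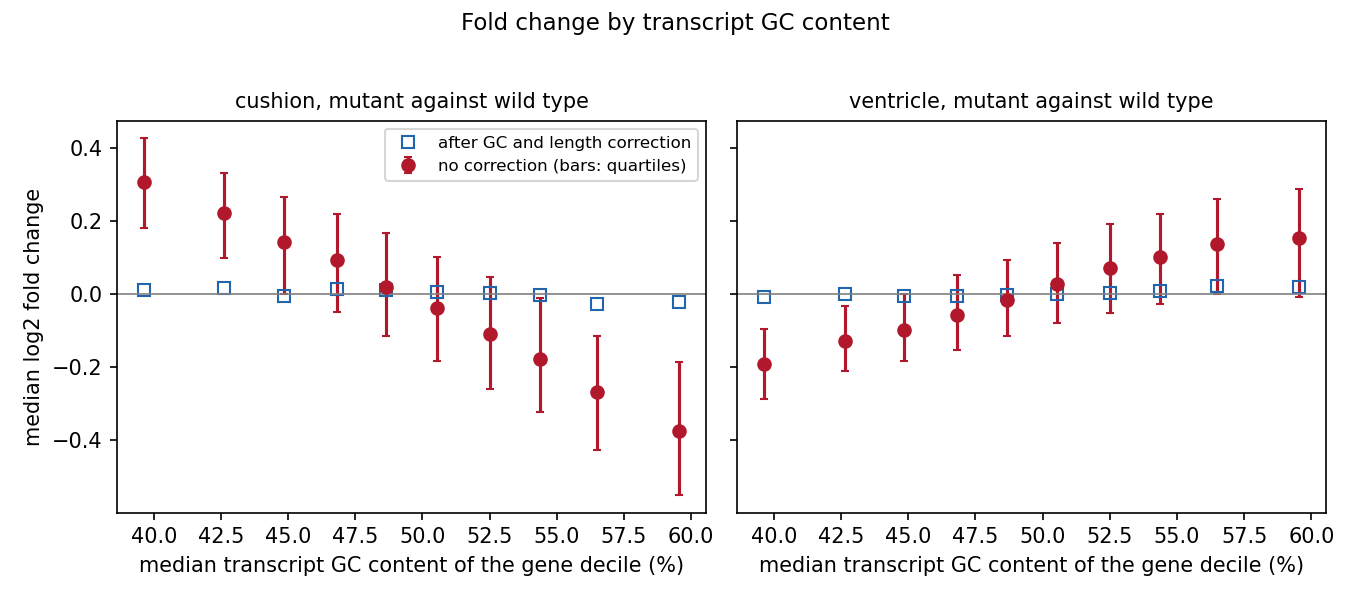
Median log2 fold change of mutant against wild type (vertical axis) in 10 equal groups of genes ordered by transcript GC content (horizontal axis, percent), in cushions and in ventricles, with filled points and quartile bars uncorrected and open squares after the GC and length correction. In cushions the median runs from 0.31 in the group lowest in GC to -0.37 in the group highest in GC, and in ventricles from -0.19 to 0.15.

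WNT target genes were lower in mutant cushions as a group. Of 16 measured members, 14 were lower and 2 higher, with a median log2 fold change of -0.56. In camera, which tests a list against the other genes, the adjusted p was 1.79e-06 with the preset correlation, and the adjusted p was 0.581 with an estimated correlation. In fry, a rotation test of the list alone, it was 0.243, and 0.0163 with the block. None of the members passed over all genes tested, and 7 fell when adjusted over the list alone. Under the block 5 fell over all genes tested and 8 adjusted over the list alone. Notum, which encodes a secreted enzyme that inactivates WNT proteins, was at 15.9 ± 1.55 CPM (SD, n = 2) in wild type and 3.68 ± 0.968 CPM (SD, n = 2) in mutants. Axin2 was at 24.1 ± 1.52 CPM (SD, n = 2) and 10.2 ± 0.322 CPM (SD, n = 2), and Nkd1 at 25.2 ± 0.113 CPM (SD, n = 2) and 11.4 ± 1.44 CPM (SD, n = 2). After the GC and length correction with the block the median of the list was -0.57. Genes at least 8-fold higher in cushion than ventricle were also lower in mutant cushions, with a median log2 fold change of -0.57 over 80 genes, and genes at least 4-fold higher in ventricle were higher, with a median of 0.77 over 24 genes. Mutant cushion replicate 2 stood apart from the other cushion libraries on the first principal component, at -22.8 against values from -54.9 to -46.3. The median log2 CPM of the 24 ventricle-enriched genes was 1.32 in it and 0.19 in mutant cushion replicate 1, against 0.14 and 0.37 in the wild type cushions.

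The WNT ligand list was lower in mutant cushions, with 7 of 10 measured members lower and a median log2 fold change of -0.46. Its camera adjusted p was 0.0256, and the adjusted p was 0.678 with an estimated correlation. None of its members passed over all genes, and 4 fell adjusted over the list alone, or 5 fell and 2 rose with the block. The list did not pass with the replicate block (adjusted p = 0.0725), without wild type cushion replicate 2 (0.205), without mutant cushion replicate 2 (0.168) or after the GC and length correction (0.0764). Besides Wnt9b, the ligand gene Wnt16 had a log2 fold change of -1.46, Wnt4 of -0.87 and Wnt7a of -1.88, none past the threshold, and with the block Wnt16 fell (adjusted p = 0.0164). Among 22 measured endothelial genes known to be raised by Klf2 or laminar flow, a list that holds Klf2 itself, 14 were lower and 8 higher. The list did not pass in camera (adjusted p = 0.123). In mutant ventricles 7 of its members were lower and 15 higher, and it did not pass there either (adjusted p = 0.332). In cushions, adjusted over the list alone, 2 rose and 3 fell, Klf2 among them, or 3 and 5 with the block. With the block over all genes Klf2, Wnt9b and Pi16 fell, Pi16 with a log2 fold change of -1.60, and Klf4, which encodes a related transcription factor, rose by 0.71. Valve matrix genes had a median log2 fold change of -0.21 over 36 members and did not pass (adjusted p = 0.11). With the block the list passed at an adjusted p of 0.00482, or 0.662 with an estimated correlation, 7 members fell and 1 rose over all genes, and 13 fell and 1 rose adjusted over the list alone. Fbln1 had a log2 fold change of -0.48 and Matn4 of -0.98, while Ogn, a small matrix proteoglycan gene, had one of 0.99. After the GC and length correction with the block 0 of the 36 passed in edgeR, and the list itself passed with an adjusted p of 0.0203, or 0.409 with an estimated correlation.

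Epicardial markers were higher in mutant cushions, with 10 of 13 members higher, a median log2 fold change of 0.52 and an adjusted p of 0.0067, or 0.678 with an estimated correlation. Wt1, a transcription factor gene of the epicardium, was at 20.6 ± 2.90 CPM (SD, n = 2) in wild type and 30.4 ± 0.142 CPM (SD, n = 2) in mutants, and Tbx18 had a log2 fold change of 0.54. Leukocyte markers were higher in 16 of 17 members, with a median of 0.41 and an adjusted p of 0.0116, or 0.768 with an estimated correlation, and included Ptprc with 0.91 and Mrc1 with 0.59. Interferon-stimulated genes were higher in 15 of 15 members, with a median of 0.71 and an adjusted p of 0.0153, or 0.768 with an estimated correlation, and included Ifit2 with 0.57 and Xaf1 with 1.19. Replication-dependent histone genes were lower in 15 of 17 members, with a median of -0.49 and an adjusted p of 0.0153, or 0.768 with an estimated correlation, and included Hist1h1a with -0.44. No member of these 4 lists passed over all genes tested or adjusted over the list alone. Under the block Tbx18 rose, and adjusted over the list alone 4 epicardial, 3 leukocyte and 1 interferon member rose. Neural and neural crest markers also passed with the block, with a median of -0.38 and an adjusted p of 0.0346, or 0.662 with an estimated correlation. Leaving out wild type cushion replicate 1 ended the call for epicardium (adjusted p = 0.185) and leukocytes (0.61), and leaving out wild type cushion replicate 2 ended it for histones (0.187). Leaving out mutant cushion replicate 2, the library that stood apart, ended the call for interferon (0.874), leukocytes (0.311) and histones (0.176). The Y-linked genes Ddx3y and Uty were higher in mutant cushions, with log2 fold changes of 0.62 and 0.56 that passed with the block and not after the GC and length correction. Kdm5d and Eif2s3y, also Y-linked, had 0.24 and 0.18 and did not pass with the block (adjusted p = 0.206 and 0.562).

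**Figure D3:**
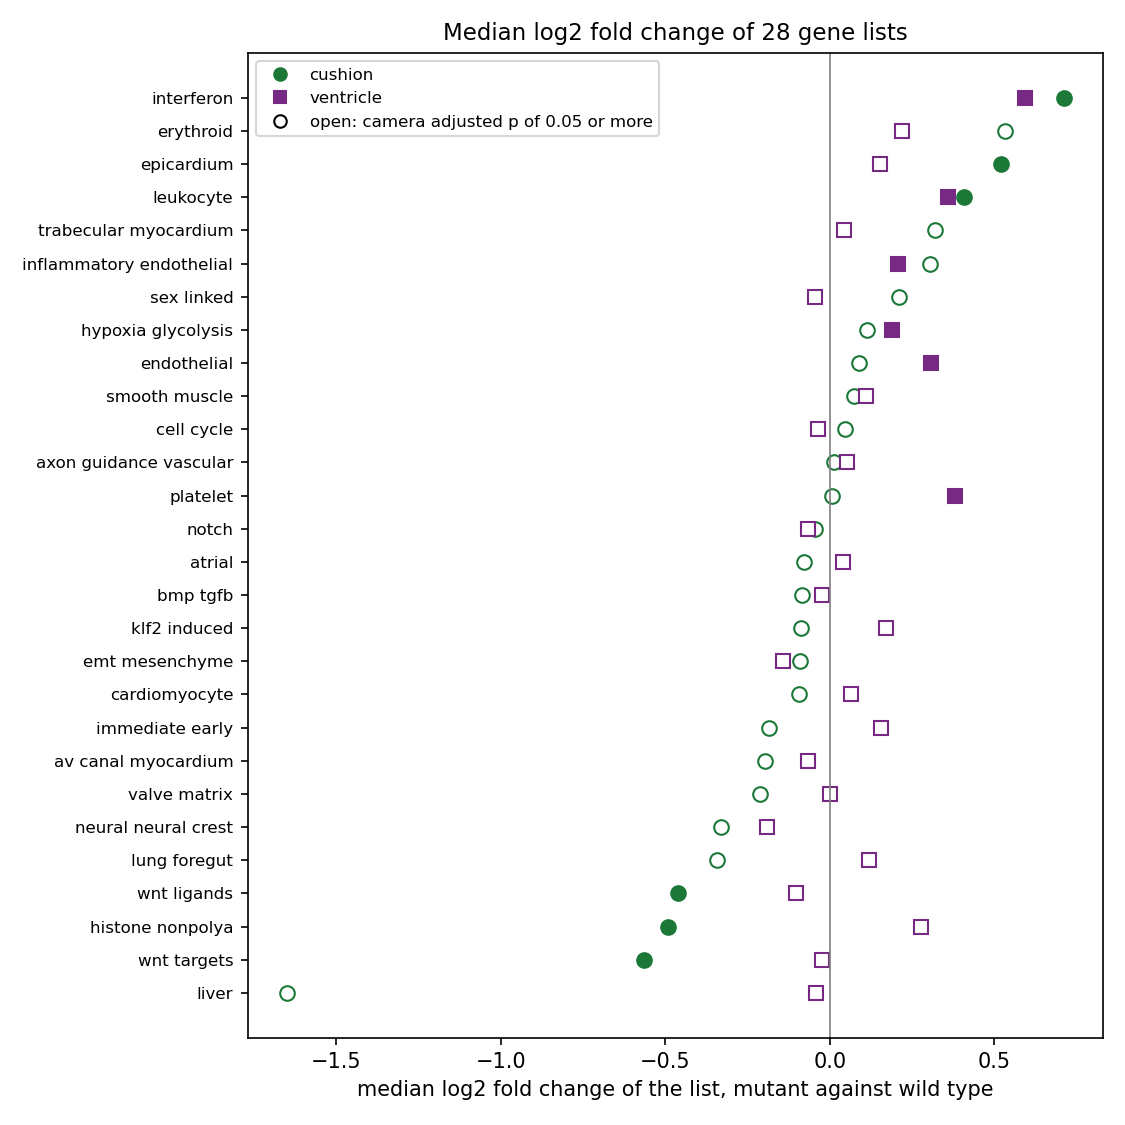
Median log2 fold change of mutant against wild type (horizontal axis) for 28 gene lists, in cushions (circles) and ventricles (squares), with filled symbols for a camera adjusted p under 0.05 at the preset correlation; none passed with an estimated correlation. WNT targets lie at -0.56 in cushions and at -0.02 in ventricles.

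The comparison of mutant with wild type ventricles puts the same genotypes side by side in the other tissue. Klf2 was the gene with the smallest p. Endothelial markers were higher in mutant ventricles as a group, with 27 of 30 members higher and a median log2 fold change of 0.31. The call was made with a preset correlation and lost with an estimated correlation (adjusted p = 0.574). Icam2, which encodes an adhesion molecule of endothelial cells, was at 34.3 ± 1.58 CPM (SD, n = 2) in wild type and 51.5 ± 12.9 CPM (SD, n = 2) in mutants, and Tie1, an endothelial receptor gene, at 99.7 ± 6.58 CPM (SD, n = 2) and 141.8 ± 25.3 CPM (SD, n = 2). Platelet, leukocyte, interferon and hypoxia genes were higher as groups too with the preset correlation. Each of these calls was lost with an estimated correlation (adjusted p = 0.72, 0.925, 0.925 and 0.72) and ended on leaving out single ventricle libraries.

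No gene passed in edgeR, and the smallest adjusted p was 0.269. An unadjusted p under 0.05 was found for 342 genes, 2.29% of those tested, or for 1088 with the block, 7.28%. With no difference a share of about 0.05 would have one. DESeq2 called 1 gene and limma-voom 0. Klf2 was the 1 call with the replicate block, and it was lost in that fit without wild type ventricle replicate 2. Without mutant cushion replicate 1 or replicate 2 the block fit made 12 calls, without mutant ventricle replicate 1 it made 11, and without wild type cushion replicate 2 it made 2. Among genes higher in mutant ventricles with the smallest p, and not passing, were Sele, which encodes E-selectin, with a log2 fold change of 1.56, Klf4 with 0.88, Mall with 1.06, Apold1 with 0.74 and Nav3 with 0.84. Among those lower were Cytl1 with -2.14, Wnt9b with -1.94, Ttc14 with -0.64 and Dhh with -1.10. Wnt9b was near the limit of counting here, at 1.97 ± 1.22 CPM (SD, n = 2) in wild type and 0.506 ± 0.21 CPM (SD, n = 2) in mutants. Nfatc1 had a log2 fold change of -0.12. Fold changes ran with GC content here in the opposite direction to cushions, with a Spearman rho of 0.458 across genes.

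The endothelial list had an adjusted p of 6.34e-07 in camera, or 0.574 with an estimated correlation, and none of its members passed over all genes or adjusted over the list alone. With the block 6 rose adjusted over the list alone. Flt4 had a log2 fold change of 0.53 and Pecam1 of 0.41. Platelet markers were higher in 10 of 10 members, with a median of 0.38 and an adjusted p of 2.80e-04, or 0.72 with an estimated correlation, and included Treml1 with 0.99 and Clec1b with 0.66. Leukocyte markers were higher in 17 of 17 members, with a median of 0.36 and an adjusted p of 0.00113, or 0.925 with an estimated correlation, and included Lyve1 with 0.95, which lymphatic endothelium also expresses, and Csf1r with 0.37. Hypoxia and glycolysis genes had a median of 0.19 and an adjusted p of 0.00205, or 0.72 with an estimated correlation, and included Ndrg1 with 0.53 and Aldoa with 0.33. Interferon-stimulated genes had a median of 0.59 and an adjusted p of 0.0068, or 0.925 with an estimated correlation, and included Oas1a, a gene with under 1 CPM in each group mean, with 1.61 and Usp18 with 1.37. Endothelial activation genes, which Klf2 is known to hold down, had a median of 0.21 and an adjusted p of 0.0113, or 0.574 with an estimated correlation, and 1 of 11 members, Sele, passed adjusted over the list alone. Ccl2, of the same list, had a log2 fold change of 0.75. In cushions the endothelial activation list had a median of 0.30, with 8 of 11 members higher, and did not pass in camera (adjusted p = 0.0543). Adjusted over the list alone 2 members rose there. Ccl2 had a cushion log2 fold change of 1.29 and rose with the block (adjusted p = 0.0338). For the interaction the list did not pass in camera (adjusted p = 0.97). No member of the platelet, leukocyte, hypoxia and interferon lists passed over all genes or adjusted over the list alone, and 3 leukocyte members rose in the latter with the block. With the replicate block erythroid markers also passed, at an adjusted p of 0.0143, or 0.929 with an estimated correlation. Leaving out single ventricle libraries ended the calls of these lists other than the endothelial one, whose adjusted p was at most 0.0054. Without wild type replicate 1 it was 0.0879 for hypoxia and 0.115 for leukocytes, and without wild type replicate 2 it was 0.228 for platelets, 0.2 for endothelial activation and 0.179 for interferon. Without mutant replicate 1 it was 0.222 for platelets and 0.288 for endothelial activation, and without mutant replicate 2 it was 0.139 for hypoxia, 0.627 for leukocytes and 0.331 for interferon, whose direction turned.

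The interaction of genotype and tissue tests whether the genotype difference was the same in cushions as in ventricles. WNT target genes differed between the tissues as a group: 15 of 16 members had a lower fold change in cushions, and the median difference was -0.60 on the log2 scale. That call was lost with an estimated correlation (adjusted p = 0.96). Notum differed by -2.44 ± 0.57 (SE), Nkd1 by -1.21 ± 0.25 (SE), Axin2 by -1.09 ± 0.32 (SE) and Apcdd1 by -0.97 ± 0.28 (SE). The mean log2 CPM of the WNT targets was 1.72 and 1.48 in wild type ventricles, against 3.55 and 3.26 in wild type cushions. A fall therefore had less room to show in ventricles. Notum was among the genes with the largest wild type fold changes toward cushion, so its ventricle values rest on few reads. Klf2 itself differed by 0.38 ± 0.62 (SE), less than its standard error. Histone genes had a lower fold change in cushions in 16 of 17 members, with a median difference of -0.80, a call also lost with an estimated correlation (adjusted p = 0.96).

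No gene passed for the interaction in edgeR. The smallest adjusted p was 0.414, 1776 genes had an unadjusted p under 0.05, or 3594 with the block, and DESeq2 and limma-voom called 0 genes. The 1776 and 3594 genes were 11.9% and 24.1% of those tested. The replicate block in edgeR called 0 genes, with a smallest adjusted p of 0.0852, while with DESeq2 it called 517. Leaving out single libraries in the edgeR block fit gave up to 1312 calls, without mutant cushion replicate 1, and also 1198 without mutant ventricle replicate 1, 391 without wild type ventricle replicate 1, 198 without mutant cushion replicate 2 and 2 without wild type cushion replicate 2. The smallest p-values belonged to Haus3, Prps2, Tmem47, Cenpw and Ttc14, with differences of 1.04, 0.96, 1.08, 0.95 and 1.15, and to Tkt, Nkd1, Emid2, Ralgds and Notum on the lower side, with Tkt at -1.22, Emid2 at -1.03 and Ralgds at -1.05. The difference between tissues ran with GC content at a Spearman rho of -0.657. The WNT target list had an adjusted p of 3.57e-04 in camera, or 0.96 with an estimated correlation, and 7.59e-04 with the block. 4 of its members passed adjusted over the list alone. The histone list had an adjusted p of 0.0211, or 0.96 with an estimated correlation, and did not pass with the block (adjusted p = 0.0637). None of its members passed adjusted over the list alone, and its call ended without replicate 2 of wild type cushion (0.097), mutant cushion (0.0904), wild type ventricle (0.184) or mutant ventricle (0.648).

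Wild type cushion and ventricle differed at many genes. Cushions were higher in cushion mesenchyme markers such as Postn, which encodes periostin, a matrix protein, at 4157 ± 955 CPM (SD, n = 2) against 399 ± 149 CPM (SD, n = 2) in ventricles, and in AV canal myocardium markers such as Tbx2 and Cacna1g. Ventricles were higher in cardiomyocyte genes such as Pln, which encodes phospholamban, and in the trabecular gene Bmp10. WNT target genes were higher in cushions, with 12 of 16 members higher at the threshold. Wnt9b was higher in cushions by 4.13 ± 0.36 (SE) on the log2 scale (adjusted p = 5.45e-04), while Klf2 did not pass, with 0.53 ± 0.36 (SE) and an adjusted p of 0.313.

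In edgeR 3452 genes passed, 1861 higher and 1591 lower in cushion, and 6180 passed with the replicate block. Leaving out wild type ventricle replicate 2 gave 739 calls, leaving out wild type cushion replicate 2 gave 1334, leaving out wild type cushion replicate 1 gave 1414 and leaving out wild type ventricle replicate 1 gave 2246. The largest fold changes toward cushion were those of Serpina3n with 6.55, Shox2, a gene of the sinus node and valve region, with 6.22, Btn1a1 with 6.09, Kcns1 with 5.50, Matn4 with 5.49, Rmst with 5.47, Notum with 5.40, Gpr50 with 5.36, Ntsr1 with 5.25 and Dpt with 5.18. Of these, Serpina3n, Kcns1 and Rmst had no read in 1 of the wild type ventricle libraries, so that their size depends on the prior count. The largest toward ventricle were those of Lrtm1 with -4.24, Sox3 with -4.21, Bmp10 with -3.38, Ifi205 with -2.998, the myoglobin gene Mb with -2.94, Slc1a1 with -2.77, Tmem88b with -2.76, Yipf7 with -2.72, Fam46d with -2.70 and Mal with -2.63. Nfatc1 had a log2 fold change of 1.14 that did not pass (adjusted p = 0.223), and rose in cushion with the block (adjusted p = 1.21e-04), and Bmp10 did not pass with the block (adjusted p = 0.058).

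Of 28 lists, 11 were higher and 5 lower in wild type cushion at the preset correlation, and the adjusted p was 0.197 or more for each list with an estimated correlation. AV canal myocardium had a median log2 fold change of 2.90, with 9 of 12 members higher at the threshold and 10 adjusted over the list alone, among them Tbx2 with 3.77 and Cacna1g with 3.77. Cushion mesenchyme had a median of 1.64, with 17 of 24 members higher, among them Msx1 with 3.90, Postn with 3.38 and Scx with 3.09. Valve matrix had a median of 1.53, with 15 of 36 members higher and 1 lower, or 28 and 2 with the block, among them Matn4, Mfap4 with 3.05 and Col6a1 with 1.78. WNT targets had a median of 1.89, among them Apcdd1 with 3.33, Axin2 with 3.07 and Nkd1 with 1.97, and WNT ligands a median of 1.95, among them Wnt4 with 2.71, Wnt2 with 2.71 and Wnt16 with 2.71. BMP and TGF-beta genes had a median of 1.11, with 2 of 23 members lower and 13 higher, among the latter Id1 with 1.87 and Id3 with 2.21. Genes raised by Klf2 or flow had a median of 0.78, with 10 of 22 members higher, or 13 higher and 2 lower with the block, among them the water channel gene Aqp1 with 3.45 and Pi16 with 3.26. Neural and neural crest markers had a median of 2.23, among them Tubb3 with 4.81 and Sox10 with 5.44. On the ventricle side, cardiomyocyte genes had a median of -0.74, with 12 of 28 members lower, or 19 lower and 1 higher with the block, among them Pln with -2.12, Gja1 with -1.84 and Hopx with -1.35. Trabecular genes had a median of -1.68, with 1 of 10 members higher and 5 lower, among the latter Sema3a with -1.27 and Irx5 with -1.88. Endothelial markers did not pass as a list (adjusted p = 0.865), with a median of 0.08 and a test direction toward ventricle. Of its 30 members 5 were lower, among them Plvap with -1.32 and Npr3 with -1.36, and 1 was higher, while with the block 7 were lower and 6 higher. Of the remaining lists past the threshold, immediate early genes had a median of 0.64, with 5 of 17 members higher, or 11 with the block, among them Ier3 with 1.30, and cell cycle genes a median of -0.19, with 6 of 26 lower, or 10 lower and 1 higher with the block, among them Rrm2 with -0.93. Epicardial markers had a median of -0.67, with 5 of 13 lower, among them Msln with -1.93, and 1 higher, Tcf21 with 1.82, or 7 and 2 with the block. Atrial markers had a median of 0.80, leukocyte markers 0.67 and interferon-stimulated genes -1.02. Leaving out wild type cushion replicate 2 ended the call for atrial markers (0.091), leukocytes (0.397) and the cell cycle (0.0563), and leaving out wild type ventricle replicate 1 ended it for atrial markers (0.0541), leukocytes (0.154) and interferon (0.106). The GC and length correction ended the call for interferon, with 0.057, or 0.0735 with the block, and with the block that for epicardium (0.0614). With the replicate block erythroid markers also passed, with a median of -1.50 and an adjusted p of 2.75e-04, or 0.481 with an estimated correlation.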

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

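The difference between tissues was tested for every gene list as planned, and the tests of explanations in this part were all chosen after the results were seen. 2 gene lists stood out because their genotype difference in cushions and in ventricles differed by a test of the interaction. For replication-dependent histone genes the adjusted p was 0.0211 in camera with the preset correlation, or 0.96 with an estimated correlation. For WNT target genes it was 3.57e-04, or 0.96 with an estimated correlation.

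WNT target genes had a median log2 fold change of -0.58 in mutant cushions and -0.03 in mutant ventricles with the replicate block. Their lower level in wild type ventricles left less room for a fall there. A trend of fold changes on GC content and transcript length is argued against as the whole cause, since the cushion median was -0.5715 after the trend was removed and the list passed in camera with an adjusted p of 2.50e-06, or 0.315 with an estimated correlation. Other tissue in the mutant cushion samples was first tested with genes at least 8-fold higher in cushion, where a median at or below that of the WNT targets would go with this cause. With the block their median was -0.5744 against -0.5778, and without it -0.5651 against -0.5646, which meets that bound. The WNT targets differed less between wild type tissues, with a median log2 fold change of 1.89, so added ventricle tissue would lower them less. Medians this close therefore decide nothing. Random lists matched on the tissue difference and on expression, a test added after the first value, put the WNT target median at percentile 2.02 of 10000 lists with the block, but at 2.53 without it, inside their central range. After the GC and length correction it was at percentile 0.04, or 0.03 without the block. The matched medians were -0.35 with the block and -0.22 after correction. The matching uses the same wild type cushion libraries as the fold change, so noise in them can lower these medians without a changed share. The median log2 CPM of ventricle-enriched genes in mutant cushion replicate 1 was 0.19, against 0.14 and 0.37 in wild type cushions, and that of WNT targets was 2.94, against 3.81 and 3.97. By their mean log2 CPM the WNT targets were at 2.90 in that library, against 3.55 and 3.26. The genes at least 8-fold higher in cushion were also lower in it, with a median log2 CPM of 2.52 against 2.99 and 2.93. The level of the ventricle-enriched genes goes against added ventricle tissue in that library, but it is 1 library. The lower level of the cushion genes leaves a smaller share of cushion tissue, or other tissue, open. In 8 of 8 runs with 1 library left out, the camera direction of the WNT targets stayed lower in mutant cushions. For the interaction it also stayed lower in each of these runs. A changed tissue share and an effect of the genotype on WNT signalling in cushions cannot be told apart. Both tests over the list met the bound for a changed share in the fit without block or correction and did not in the others. Without the correction their values lay too close to the bounds to decide, and both explanations stay open.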

How the results depend on the processing

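The alternatives with a GC and length correction, with summed or separate rows of a symbol, and with the block combined with another choice were chosen after seeing the data; the others were planned. Gene counts without a block in cushions, 0 in edgeR, were 25 with DESeq2, 2 with limma-voom, 5 without a filter and 1 with the compared groups alone; in ventricles, also 0, they were 1 with DESeq2 and 1 with the compared groups alone. With the replicate block, which treats the shared numbers as a pairing, counts were 129 in cushions, 1 in ventricles, 0 for the interaction and 6180 for tissue. With a block by tissue they were 879, 18, 710 and 5184. With the block and DESeq2 they were 372, 9, 517 and 5310, and with the block and the GC and length correction 71, 1, 0 and 5999. The block fit has 3 residual degrees of freedom, against 4 without it. For the changed counts the cause was not tested.

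Leaving out each library leaves 1 group with a single sample, which is assumed to vary like the others. The counts then ranged over 0 to 1 in cushions, 0 to 1 in ventricles, 0 to 0 for the interaction and 739 to 3498 for tissue, and with the replicate block over 25 to 891, 0 to 12, 0 to 1312 and 3037 to 6824. Of the 129 block calls in cushions, 120 were also called by DESeq2 with the block, 120 by limma-voom, 129 with DESeq2 size factors, 114 with summed rows and 45 after the GC and length correction. Without mutant cushion replicate 1, 116 of them were among the 891 calls, and without wild type cushion replicate 2, 15 were among the 25.

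Gene lists past the threshold in cushions, ventricles, the interaction and tissue numbered 6, 6, 2 and 16 with camera. With an estimated correlation they numbered 0, 0, 0 and 0, and with fry 0, 0, 0 and 12. Under the replicate block they numbered 7, 7, 1 and 17 with camera, where the block changed no list call other than those named with the results, and 1, 0, 0 and 17 with fry. The fry calls gained with the block were WNT targets in cushions (0.0163), and for tissue valve matrix (0.00184), vascular axon guidance (0.0154), leukocyte and erythroid markers (0.0336 each) and Notch genes (0.0479). The GC and length correction gave 12 in cushions, or 12 with the block, and 3 for the interaction, or 1 with the block. Gained in cushions were hypoxia and glycolysis (0.00437, or 0.00727 with the block), endothelial markers (7.03e-04 and 0.0011), cushion mesenchyme and liver in both fits, neural markers, Notch genes and endothelial activation only without the block, and erythroid markers only with it. With the block, neural markers passed both before the correction (0.0346) and after it (0.0118). The 3 for the interaction were WNT targets, histone genes and platelet markers, and the platelet call (0.0231) was gained. In the corrected fit with the block and an estimated correlation, the adjusted p in cushions was 0.409 for mesenchyme, liver and neural markers, 0.451 for Notch, 0.472 for endothelial activation, 0.56 for hypoxia, 0.732 for endothelial and 0.744 for erythroid markers, and for the platelet interaction 0.926. Over left-out libraries the numbers ranged from 6 to 12, 6 to 8, 1 to 8 and 13 to 18.

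Directions turned for single genes far from the threshold. Over left-out libraries the log2 fold change of Nfatc1 in ventricles ranged from -0.95 to 0.65, above 0 without wild type ventricle replicate 1 (0.65) or mutant ventricle replicate 2 (0.40), and it was 0.016 with summed rows. Lef1 in ventricles ranged from -1.03 to 0.12, above 0 without wild type ventricle replicate 1. For the interaction, Klf2 ranged from -0.59, without mutant cushion replicate 1, to 0.99. Nfatc1 ranged from -1.19 to 0.41 and Wnt9b from -1.24 to 0.14, above 0 without wild type ventricle replicate 2 (0.07 and 0.14) or mutant ventricle replicate 1 (0.41 and 0.12). The cause was not tested. A pseudocount alternative, planned for normalized values only, does not apply to counts.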

Other observations

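The contrast averaged over tissues and the tests in this part were all chosen after the data were seen, and so were the genes named from that contrast. Averaged over cushions and ventricles, Klf2 fell with a log2 fold change of -3.73 and Dpt with -1.68 in edgeR, with adjusted p = 0.0203 and 0.0395, the 2 calls made without a block. Under the replicate block 31 genes passed, of which 16 rose and 15 fell. Among those that fell were Wnt9b with -2.12, Apcdd1 with -0.98, Cytl1 with -1.78, Lef1, a transcription factor gene of WNT signalling, with -0.95, Mstn, which encodes myostatin, with -1.02 and the protease gene Htra1 with -0.66. Among those that rose were Klf4 with 0.79, Apold1 with 0.85, the adhesion gene Sele with 1.21, the chemokine gene Ccl2 with 1.02, and Gimap4 and Gimap6 with 0.69 and 0.66. Tsix, whose counts are uncertain because the strand setting is unknown, also fell with -0.77, and the Y-linked gene Ddx3y also rose with 0.42. Whether the groups differed in the sex of the embryos was not tested. Of the 44 genes that rose with the block in cushions, 24 (54.55%) were higher in mutant ventricles, and of the 85 that fell, 50 (58.82%) were lower there. Their median ventricle log2 fold changes were small, at 0.04 and -0.09. The share over all genes was not computed, so these counts do not show an effect shared by both tissues.

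Lists for several other cell types and pathways had no call between genotypes in either tissue when all libraries were used without a GC and length correction. In cushions BMP and TGF-beta genes had a median log2 fold change of -0.08 (adjusted p = 0.312), cardiomyocyte genes of -0.09 (0.312), cushion mesenchyme of -0.09 (0.176), AV canal myocardium of -0.20 (0.104), Notch genes of -0.05 (0.862) and liver markers of -1.65 (0.0706). With single libraries left out, lower levels passed in cushions for cardiomyocyte genes in 1 of 8 runs (lowest adjusted p = 0.00199), cushion mesenchyme in 2 (0.00748) and liver markers in 2 (0.0138), and in ventricles for cushion mesenchyme in 2 (0.0225) and AV canal myocardium in 1 (0.0375). After the GC and length correction the adjusted p in cushions was 0.0314 for cushion mesenchyme and 0.0116 for liver, both lower, and with the replicate block 0.00637 and 0.0137, or 0.409 for each with an estimated correlation. Notch genes changed direction with the correction, to a median of 0.15 with the block and 12 of 17 members higher, and had an adjusted p of 0.049, or 0.0839 with the block and 0.451 with an estimated correlation. Hypoxia and glycolysis genes, higher as a group in ventricles, had an adjusted p of 0.255 in cushions, and of 0.00437 after the correction. With the block added 15 of 17 members were higher, with a median of 0.15 and an adjusted p of 0.00727, or 0.56 with an estimated correlation. Endothelial markers in cushions had a median of 0.09 (0.33), and after the GC and length correction with the replicate block a median of 0.21, with 25 of 30 higher and an adjusted p of 0.0011 in camera, or 0.732 with an estimated correlation.

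Valve matrix genes were lower in mutant cushions with the replicate block, with a median log2 fold change of -0.22. Their mean log2 CPM was 7.778 and 7.105 in wild type cushion replicates 1 and 2, and 7.682 and 6.727 in mutant cushion replicates 1 and 2. The difference was thus larger between the replicates 2. The direction of the list in camera was not the same over all alternative fits and left-out libraries. After the GC and length correction the median was -0.1346, the list passed in camera with an adjusted p of 0.0203, or 0.409 with an estimated correlation, and 0 members passed, against 7 that fell before, so that a part of this difference may follow the GC trend. Lists matched on the tissue difference and on expression had a median of -0.25, and the valve matrix median lay at percentile 66.97 of them, or 50.6 after correction. This cannot decide on a changed share of cushion tissue in the mutant samples. The matching and the fold change use the same wild type cushion libraries, so noise in them can lower the matched lists. An effect of the genotype on cushion genes at large could also give such percentiles. An effect of the genotype on matrix genes was not tested apart from these.

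Endothelial markers were higher in mutant ventricles. The trend on GC content and length is not the whole cause, as the median of 30 markers was 0.2894 after correction and the list passed in camera with an adjusted p of 4.00e-06, or 0.907 with an estimated correlation. A lower share of cardiomyocytes would raise markers of other cell types alike. Endothelial and cushion mesenchyme markers differed by 0.4524 in their medians, 0.30 against -0.15, with the replicate block. A two-sided permutation test over the 30 and 24 members gave p = 1e-05, the smallest value that 100000 resamples can give. It treats members as independent, though they were measured in the same libraries, so its p does not measure the spread between samples. Epicardial, erythroid, smooth muscle and lung or foregut markers were higher too (medians 0.16, 0.23, 0.09 and 0.11). So were cardiomyocyte, atrial and trabecular genes (0.05, 0.08 and 0.04). Neural, AV canal and liver markers were lower (-0.21, -0.08 and -0.05). These values do not settle whether cardiomyocytes had a lower share. Platelet and leukocyte markers were also higher, with medians of 0.38 and 0.33, so that more vessels or more blood in the samples, and an effect of the genotype on endothelial genes, may each contribute and stay open. The list call rests on the preset correlation, since without the block and the correction the list did not pass with an estimated correlation either (adjusted p = 0.574).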
